A study of Mus musculus with 6 samples.

How the data were processed

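Exosomal RNA of NK cells from 3 stressed and 3 unstressed samples was measured on 1-colour Agilent mouse miRNA arrays, and samples were grouped by their titles in the labels. Scanner files were made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers, with background subtracted and spatially detrended and with mm9 as the genome build of the array annotation. The scanner values are intensity on a linear scale, not normalized between arrays, per the file headers. A table deposited by the authors for the whole series gives a raw total signal per miRNA (intensity, with 0.1 for a miRNA not detected), a normalized value (log2) and a detection call. The authors do not state in the sources used here how the normalized log2 values were made. Set against the raw totals of the same table, they equalled quantile normalization of the log2 raw totals over all 1902 entries, controls included, with a largest deviation of 1.96e-05. The log2 values of the series matrix that the authors deposited equalled the normalized values of that table exactly (deviation 0), and their medians were -3.32, -3.31 and -3.31 on the stressed arrays and -2.46, -2.43 and -2.30 on the unstressed arrays. Scale (log2) and direction are therefore known for the series matrix, and no centring per miRNA was found. All columns with per-sample values in these tables were matched to a sample.

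Scanner signals (background-subtracted) of non-control spots without an outlier flag were averaged per probe. A probe was taken as detected on an array when over a share of 0.5 of its spots were well above background, and a miRNA when 1 of its probes was. Each array was divided by the 75th percentile of the signal over the 49 probes detected on all arrays, which was 6.37 ± 0.244 on the stressed and 0.159 ± 0.0262 on the unstressed arrays (SD, n = 3, relative to the geometric mean of the percentile over arrays). The scaled signal was then floored at the highest, over arrays, of the lowest scaled signal of a detected probe, and log2 was taken. Where all arrays of a group lay at this floor, the difference is a lower bound and is written as at least its size, or as the bound from the lowest signal well above background where no array of that group detected the miRNA. Because the unstressed arrays were multiplied up, this floor lay high (115.571 in scaled units, set by unstressed replicate 3) and 327 of the 431 tested miRNAs sat at it on all arrays. A miRNA took the probe with the highest mean over arrays, with ties at the floor broken by the unscaled signal; 19 of the 1881 miRNAs took another probe without scaling. A miRNA was tested when detected on every array of at least 1 group.

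Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with group as the only term. A miRNA at the same value on all arrays (within 1e-09 log2) was given a difference of 0 and an adjusted p of 1 in limma; such miRNAs were counted in the adjustment and were left out of the variance estimate and of the list tests, since rounding error in them distorted limma's prior; this was decided after values had been seen, and the other way is among the alternatives. Single measures were compared with exact two-sided permutation tests, whose smallest p is 0.1 here. Lists were tested with camera (preset correlation 0.01, at least 2 tested members), with camera using an estimated correlation, and with fry, whose p-value asks whether a list's miRNAs move, on balance, one way. The lists were miR-207, the let-7 family, the miR-17 to miR-92 clusters and paralogues, lymphocyte and NK cell miRNAs, inflammation-regulated miRNAs, neuronal and stress-studied miRNAs, markers of erythroid, myeloid, endothelial and platelet, hepatocyte, muscle, stromal and epithelial cells, the Dlk1-Dio3 imprinted cluster, the families of the Sfmbt2 cluster by name, and GC-rich miRNAs often bright on arrays. miR-155-5p and miR-21a-5p stand in both the lymphocyte and the inflammation list. Named miRNAs were miR-207, up to 12 per direction with the largest difference among called miRNAs whose groups did not overlap, the 5 with the highest mean in each group, and up to 4 tested members per list with the smallest p-value; miR-342-3p, further members of lists, miRNAs named because a count held few of them, and miRNAs detected on no array were chosen after their values were seen. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

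The limma and list steps were tested on simulated data for the comparison of stressed with unstressed arrays, run on 431 miRNAs. Of 100 simulated changes of 1 on the log2 scale 98% were recovered, and of 100 changes of 2 it was 100%, while 3.88% of the calls were false. The simulated values had the means and spreads of the unscaled fit, the same spread in both groups and no floor. These rates therefore do not describe the percentile-scaled comparison, in which most tested miRNAs lay at the floor. Lists shifted by 1 were called up in 100% of cases. Unshifted lists were called up in 0%, and calls of such lists as down were not counted, so this is no full rate of false calls. Alternatives covered the background, the scaling, the probe summary, the filter on low signal, the detection flag, the floor, the limma settings, the deposited values as input, the replicate number as a block and each array left out. Scaling by the spike-ins was added after the data had been seen. With hybridisation spike-in scaling the array offsets were shared by all miRNAs and limma's prior degrees of freedom were infinite, so its adjusted p-values there treat shared offsets as independent error and are too small; single ones are given only for miR-207 and the lists, and the counts of calls with that scaling rest on them too. The number of arrays limits the precision, and signals near background limit what could be measured in the unstressed group. Files were read with the R package data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Positions of probe targets come from the array annotation (mm9); the gene table used for Mir207 belongs to another assembly, GRCm38.p6, so it was used for names and neighbours only.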

Results

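MicroRNAs carried by exosomes, the small vesicles that cells release, were measured for natural killer (NK) cells taken from stressed and unstressed mice. The cells had been kept in culture for 48 h before the vesicles were collected, and 0.2 µg of RNA was labelled with Cy3 for each array, per the labels. The labelling kit they name is a linear amplification kit of a kind usual for messenger RNA arrays, so how the miRNAs were labelled, and what amount of miRNA the 0.2 µg stands for, is uncertain. Each group held 3 Agilent 1-colour mouse arrays, and each array carried 4415 probes for 1881 mouse miRNAs on 56430 spots. No spot was saturated on any of the 6 arrays. All 6 arrays lay on 1 slide, the stressed group in row 2 and the unstressed group in row 1, so the row of the slide and the group cannot be told apart. The labels do not say that each array held RNA of a separate animal, so p-values measure at most the spread between these samples, which may be technical. Where the floor held all arrays of a group at the same value, limma's p-values leave out that group's spread. The number of arrays limits the precision.

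The first comparison asked how many miRNAs each exosome preparation held above background. Stressed exosomes gave 440 ± 12.1 detected miRNAs per array (SD, n = 3) and unstressed exosomes 52.7 ± 12.1 (SD, n = 3), an 8.35-fold difference. The single arrays gave 453, 438 and 429 miRNAs in the stressed group and 62, 57 and 39 in the unstressed group. The summed miRNA signal was 159-fold higher on the stressed arrays, where 5 miRNAs took 74.8% ± 0.502 of it, against 42.7% ± 5.54 on the unstressed arrays (SD, n = 3). The exact two-sided permutation test gave p = 0.1 for the number of miRNAs, for the summed signal and for the share of the 5 brightest, which is the smallest value that 3 arrays against 3 can give. Spike-in RNA did not follow this difference. The labelling spike-ins dmr_285 and dmr_31a differed by 0.23 and -0.07 on the log2 scale (stressed minus unstressed), and the hybridisation spike-ins dmr_3 and dmr_6 by -0.36 and -0.41. Replicate arrays lay close together in the stressed group, with a median SD of 0.056 log2 over 420 miRNAs, and less so in the unstressed group, with 0.22 log2 over 39. With the scanner software's own gene call the means were 518 and 89.3, and with its positive-and-significant flag 738 and 279.

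**Figure D1:**
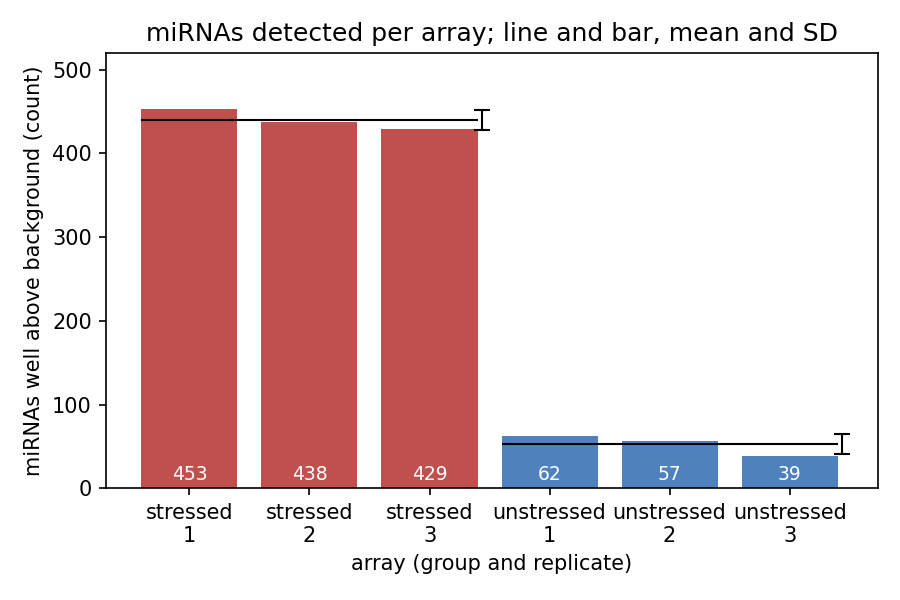
Number of mouse miRNAs well above background (vertical axis, count) on each of the 6 arrays (horizontal axis), with each group's mean as a line and its SD as a bar. The 3 stressed arrays held between 429 and 453 miRNAs and the 3 unstressed arrays between 39 and 62.

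Most detected miRNAs were seen in 1 group only. In all, 376 miRNAs were detected on all 3 stressed arrays and on no unstressed array, 7 showed the opposite, 30 were detected on all 6 arrays and 1408 on none. Because the dim group gives no more than a bound, folds are written as "at least": the brighter group's mean log2 value was set against, for each dim array, the higher of its lowest signal among probes well above background and the dim probe's own signal. Limma p-values given beside these bounds test the differences of floored values, not the bounds. Before any scaling between arrays the median bound for the 376 was at least 5.29-fold, and miR-7118-5p reached at least 1290-fold (limma adjusted p = 8.7e-12). miR-7008-5p reached at least 894-fold and miR-5100 at least 740-fold on the same scale. After each array was divided by its own 75th percentile the bound stayed above 1 for 65 of the 376, and miR-7118-5p was at least 31.8-fold higher (limma adjusted p = 4.9e-09). Limma called 373 of the 376 without scaling and 53 with it. The 376 were picked by detection on these same arrays, so the direction of the calls without scaling was all but set. Of all 431 tested miRNAs, 415 were called higher without scaling. These counts and p-values are therefore no separate support for the set. The 7 miRNAs detected in unstressed exosomes only were miR-466f-3p, miR-466g, miR-466h-3p, miR-466i-3p, miR-466q, miR-467f and miR-669p-3p, which all belong to the families of the Sfmbt2 cluster. The count depended on 1 array and on the detection flag: it was 12 without unstressed replicate 3, also 12 with detection on at least 2 of 3 arrays, and 19 with the positive-and-significant flag, with 4, 4 and 9 of them outside these families. Among the 7, miR-466h-3p was at least 4.68-fold higher in unstressed exosomes without scaling and at least 190-fold higher with it. The floored log2 differences that limma tested were -2.20 without scaling (adjusted p = 2.5e-04) and -2.09 with it (adjusted p = 3.4e-04). 6 of the 7 passed on either scale, the exception being miR-669p-3p (adjusted p = 0.0574 and 0.228). The 7 were picked by detection in the same way, so these calls too are no separate support.

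Apart from miR-207, the Sfmbt2 families and the GC-rich list, no member of the families and cell type markers fixed beforehand was detected on an unstressed array. Of the 10 members of the let-7 family, 7 were detected on all stressed arrays and none on an unstressed array. Members tested on this ground, here and in the lists described next, could not come out lower without scaling. Their unstressed values lay at the floor, so the direction of those calls was set beforehand. Without scaling let-7b-5p was at least 8.84-fold and let-7a-5p at least 2.18-fold higher in stressed exosomes, and all 7 were called higher (7 also when adjusted over the list alone), whereas after scaling all 7 lay at the floor on every array and none was called. The same held for each of the groups described next: after scaling none of their tested members was above the floor on any array, none was called (adjusted p = 1; 0 when adjusted over the list alone, with 0 at unadjusted p under 0.05), and no camera test could be made. Of the 22 lymphocyte and NK cell miRNAs on the array, 5 were detected on all stressed arrays: miR-155-5p, a regulator of lymphocyte activation (at least 8.63-fold without scaling), miR-21a-5p (at least 8.76-fold), miR-29a-3p (at least 5.32-fold), miR-342-3p (at least 3.23-fold) and miR-15b-5p (at least 1.54-fold). In the same list 16 miRNAs were detected on no array, among them miR-150-5p, miR-16-5p, miR-142a-3p and miR-146a-5p, which are abundant in lymphocytes. Of the 12 members of the miR-17 to miR-92 clusters and their paralogues, 3 were detected on all stressed arrays, with miR-92a-3p at least 7.08-fold, miR-25-3p at least 1.59-fold and miR-106b-5p at least 1.35-fold higher without scaling. The inflammation-regulated list had 3 of 11 such members (miR-155-5p, miR-21a-5p and miR-223-3p). The neuronal and stress-studied list had 2 of 16, miR-134-5p (at least 41.6-fold) and miR-34a-5p (at least 1.31-fold), and the Dlk1-Dio3 imprinted cluster had 2 of 21, miR-134-5p and miR-382-5p (at least 1.57-fold).

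Markers of other cell types moved the same way. The erythroid markers had 3 of 5 members detected on all stressed arrays and none on an unstressed array, with miR-451a at least 5.31-fold, miR-486a-5p at least 4.11-fold and miR-486a-3p at least 2.66-fold higher without scaling. The muscle markers had 3 of 4, with miR-206-3p at least 6.07-fold, miR-133b-3p at least 1.36-fold and miR-133a-3p at least 1.33-fold higher. Of the 2 myeloid markers miR-223-3p was at least 3.08-fold higher. The 2 endothelial and platelet markers, the hepatocyte marker miR-122-5p, the 5 stromal markers and the 6 epithelial markers were detected on no array. Without scaling limma called every tested member of these lists higher in stressed exosomes, and fry, which asks whether the miRNAs of a list move, on balance, one way, called all 10 lists with at least 2 tested members up. For the marker lists this direction was set beforehand. Their members were tested because all stressed arrays detected them, and their unstressed values lay at the floor. These calls therefore add no support beyond the detection itself. Camera, which compares a list with the other tested miRNAs, called none of the marker lists, the let-7 family or the lymphocyte list without scaling, where the median tested miRNA was itself 2.23 higher on the log2 scale.

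**Figure D2:**
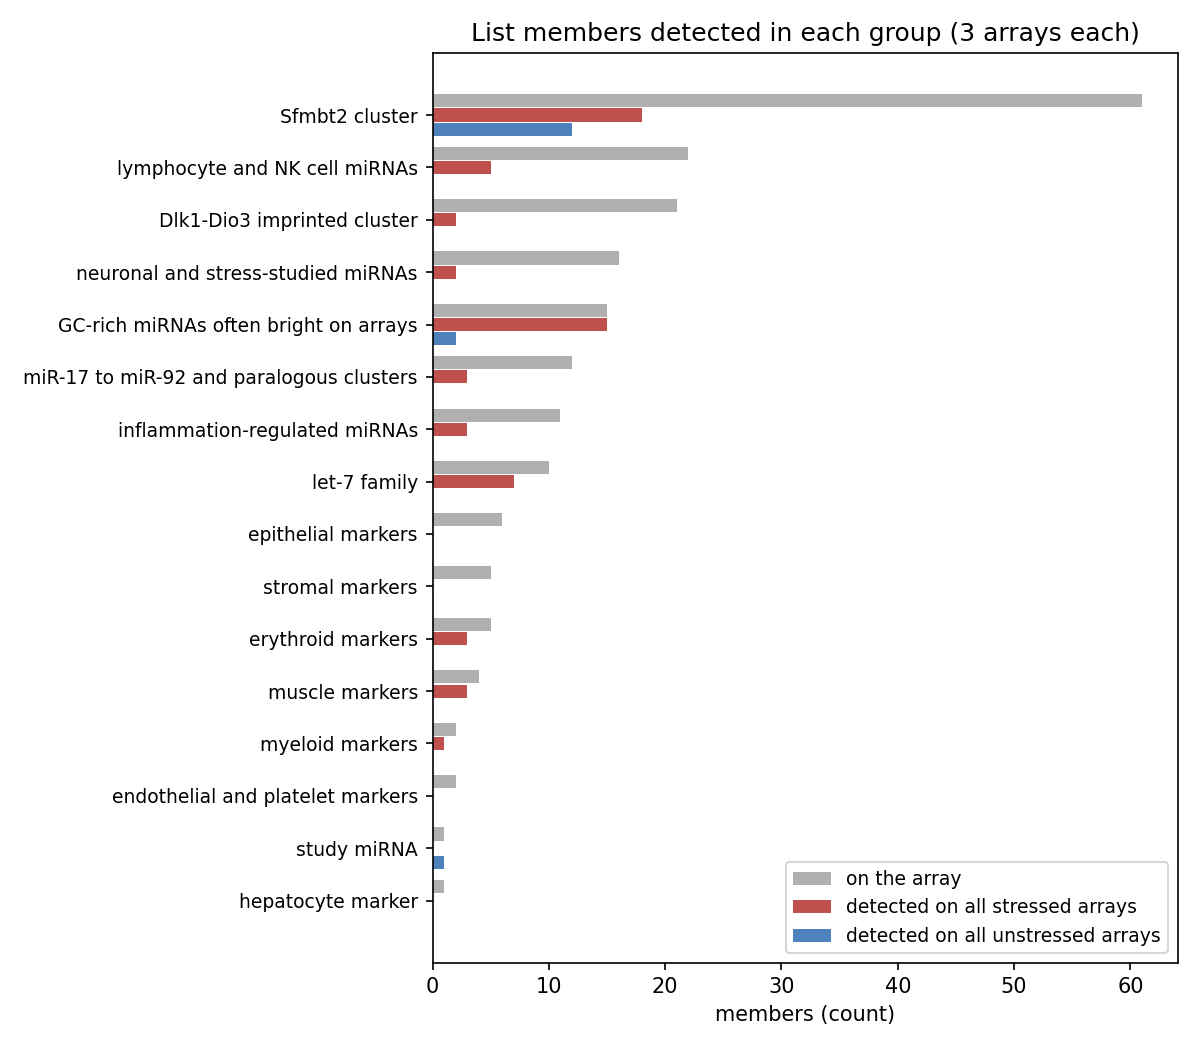
Members of each list (horizontal axis, count) that the array carries, that were detected on all 3 stressed arrays and that were detected on all 3 unstressed arrays. Members were detected on all 3 unstressed arrays in 3 lists: 12 of the Sfmbt2 cluster families, 2 of the GC-rich miRNAs and miR-207.

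Relative to the 75th percentile of their own array, 5 of the 12 miRNAs with the largest increases on the floored scale belonged to the list of GC-rich miRNAs, namely miR-1224-5p, miR-3960, miR-5126, miR-7118-5p and miR-5100. Of the 431 miRNAs tested with limma, 63 rose and 22 fell in stressed exosomes. For 55 of the 63 all unstressed arrays lay at the floor, and for 18 of the 22 all stressed arrays did, so that their differences are lower bounds with no order among them. The floor gives such a group a spread of 0, so limma's p-values for these miRNAs understate the spread between samples. miR-1224-5p rose by 7.38 on the log2 scale (SE 0.18, adjusted p = 2.0e-06), miR-8110 by 5.96 (SE 0.11), miR-5126 by 5.19 (SE 0.024) and miR-5110 by 4.49 (SE 0.14), all measured above the floor in both groups. miR-3960, detected on 1 of 3 unstressed arrays but at the floor on all 3, rose by at least 7.03 (adjusted p = 4.9e-09). On the scanner miR-1224-5p read 291933 ± 6653 in stressed and 43.5 ± 6.11 in unstressed exosomes (SD, n = 3). The other miRNAs among these 12 were miR-7118-5p, miR-7008-5p, miR-5100, miR-211-3p, miR-6769b-5p, miR-6931-5p and miR-7047-5p, with bounds of at least 12.2-fold to at least 31.8-fold. The array annotation (mm9) places the probe target of miR-1224-5p at chromosome 16, 20604536 to 20604545, and that of miR-211-3p at chromosome 7, 71350763 to 71350774, and gives no position for the others of the 12.

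The miRNAs that fell after scaling split by what the scanner had read. miR-466i-5p fell by 5.35 on the log2 scale (SE 0.28, adjusted p = 5.8e-05) although its scanner signal was alike in the groups, 1453 ± 212 in stressed and 1547 ± 640 in unstressed exosomes (SD, n = 3), and it was 0.39 higher with spike-in scaling. miR-3082-5p fell by 4.35 (SE 0.21; 1 of 3 stressed arrays at the floor) and miR-574-5p by 4.11 (SE 0.28) after scaling. With all stressed arrays at the floor, miR-1187 fell by at least 3.22, miR-6904-5p by at least 2.28, miR-669n by at least 1.93 and miR-6918-5p by at least 1.34. Yet each of these 6 was higher in stressed exosomes without scaling, by 0.90, 1.24, 1.67, 2.82, 2.75 and 3.51 for miR-3082-5p, miR-574-5p, miR-1187, miR-6904-5p, miR-669n and miR-6918-5p. In contrast miR-466h-3p, miR-466f-3p, miR-467f and miR-466i-3p, not well above background on any stressed array, were lower both with scaling (by the bound at least 190-fold, 149-fold, 111-fold and 101-fold) and without it (at least 4.68-fold, 3.67-fold, 2.74-fold and 2.50-fold). miR-877-3p, at the floor on all stressed arrays after scaling, was also lower on both scales, as was miR-466g (adjusted p = 0.00138 and 0.026 with scaling). The array annotation (mm9) places the target of miR-669n at chromosome 2, 10430951 to 10430967, that of miR-466i-3p at chromosome 13, 17839390 to 17839407, and that of miR-877-3p at chromosome 17, 36097743 to 36097758. Of the 22 miRNAs that fell, 12 were called higher without scaling, 8 were called lower and 2 were not called.

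**Figure D3:**
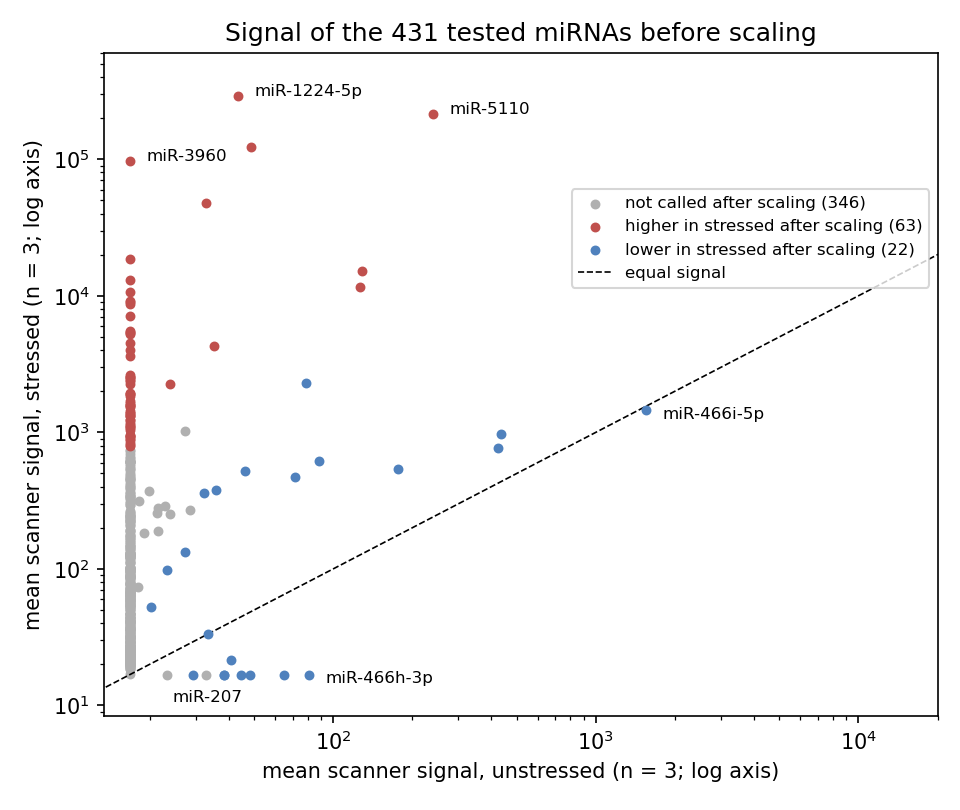
Mean scanner signal of each of the 431 tested miRNAs in unstressed (horizontal log axis) and stressed exosomes (vertical log axis, n = 3 each) before scaling, coloured by the call after scaling; means below a signal of 16.8 are drawn at 16.8. All 63 miRNAs called higher lie above the dashed line of equal signal, and of the 22 called lower, 12 were called higher without scaling.

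The balance of these calls followed the scaling. The split was 63 higher and 22 lower with the 75th percentile of probes detected on all arrays, 134 and 11 with the percentile of all probes, 384 and 28 with quantile normalization, 372 and 8 with hybridisation spike-ins (where limma's prior made p-values too small), 406 and 10 with labelling spike-ins, and 415 and 8 without scaling. The median difference over tested miRNAs was 0 for both percentiles and 0.97, 2.06, 2.15 and 2.23 for quantile, hybridisation spike-in, labelling spike-in and no scaling. Under all 6 of these settings, and equally under the 5 without hybridisation spike-ins, 59 miRNAs rose and 6 fell, the 6 being miR-466f-3p, miR-466g, miR-466h-3p, miR-466i-3p, miR-467f and miR-877-3p. Not all of these falls held beyond the scaling. Over all alternatives miR-466i-3p kept its call in 16 and lost it in 10, and miR-467f kept it in 18 and lost it in 8. miR-466f-3p and miR-877-3p lost it in 1 each. With an unadjusted p under 0.05 and at least a 2-fold difference, 40 miRNAs were higher and 12 lower after percentile scaling, and 65 and 22 without unstressed replicate 3. 327 of the 431 tested miRNAs lay at the floor on all arrays after that scaling and could not be called, and leaving out unstressed replicate 3 raised the count of 22 lower miRNAs at the adjusted threshold to 39, whereas leaving out stressed replicate 1, 2 or 3 lowered it to 13, 13 and 14.

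A pair of the lists could be compared with the other miRNAs after percentile scaling. Camera with the preset correlation called 2 lists in each of the 10 ways of splitting the 6 arrays into 3 and 3. Its calls after this scaling therefore cannot be tied to stress. Of the 25 tested members of the miR-297, miR-466, miR-467 and miR-669 families, many of which come from the Sfmbt2 cluster, 8 fell, none rose and 17 did not pass (0 higher at unadjusted p under 0.05; 8 lower when adjusted over the list alone). Camera placed this list below the other miRNAs (median -0.22, adjusted p = 4.6e-07), but adjusted p = 0.216 with an estimated correlation, and over the alternatives camera's adjusted p ran from 7.5e-18 to 0.352. Without scaling 17 of the 25 were called higher and 6 lower, the median was 2.56 and fry called the list up, on a scale where the scale factors of the groups, 5.34 apart in log2, were not divided out of any miRNA. Camera placed it below the other miRNAs there too (adjusted p = 9.2e-12), but adjusted p = 0.932 with an estimated correlation, and with hybridisation spike-ins camera's call was lost (adjusted p = 0.352). All 15 miRNAs of a list that is often bright on arrays for GC-rich sequence, fixed as a technical list, were tested: 10 rose, among them miR-2137 (at least 9.20-fold), miR-2861 (at least 6.84-fold) and miR-3963 (at least 3.87-fold), none fell and 5 did not pass (10 higher when adjusted over the list alone). Camera placed it above the other miRNAs (median 1.63, adjusted p = 0.00256), but adjusted p = 0.216 with an estimated correlation, and over the alternatives camera's adjusted p ran from 1.4e-08 to 0.586. After scaling fry called the first list down (adjusted p = 0.00636) and the second up (adjusted p = 8.2e-09).

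The study's title names miR-207, and its level was compared directly. On the scanner miR-207 read 15.2 ± 2.51 in stressed and 29.3 ± 8.11 in unstressed exosomes (SD, n = 3), close to the background, and it was well above background on 1 of 3 stressed and 3 of 3 unstressed arrays. After percentile scaling miR-207 fell by at least 0.65 on the log2 scale (limma adjusted p = 0.0137), a bound set by the floor, at which all 3 stressed arrays lay. Without the floor the scaled signal was 2.39 ± 0.466 in stressed and 183 ± 27.4 in unstressed exosomes (SD, n = 3), a 76.5-fold gap that rests on stressed values close to background and on scale factors 40.2-fold apart. On the probe used here all 3 unstressed arrays lay above all 3 stressed arrays, and the exact two-sided permutation test gave p = 0.1, its smallest value. Another miR-207 probe, A_54_P1182, overlapped on the scanner, with 16.3 on stressed replicate 2 and 15.9 on unstressed replicate 3. The remaining probes of miR-207 did not overlap. The difference was -0.73 without scaling (adjusted p = 0.016), -0.77 with labelling spike-ins (adjusted p = 0.011) and -0.25 with hybridisation spike-ins, where it did not pass (adjusted p = 0.113; exact permutation p = 0.4). These values were floored too. Without scaling the floor was 16.8, and stressed replicates 1 and 3 read 15.1 and 12.7. The floor thus limited that difference and narrowed the stressed spread behind its p-value. It passed no longer with normexp background (-0.10, adjusted p = 0.147), the mean over its probes (-0.44, adjusted p = 0.203), the percentile of all probes (-0.78, adjusted p = 0.0577), no filter on low signal (adjusted p = 0.0602) or a floor 2 times as high, where all arrays were at the floor, and over all alternatives the adjusted p ran from 3.1e-09 to 1. The fall was larger with quantile normalization (-3.99, adjusted p = 3.1e-09), with the positive-and-significant flag (-3.80, adjusted p = 2.1e-07) and with a floor 0.5 times as high (-1.65, adjusted p = 1.3e-04). Leaving out any 1 stressed array, or unstressed replicate 2, also ended the call (adjusted p = 0.0932, 0.0708 and 0.0755 without stressed replicates 1, 2 and 3, and 0.0700 without unstressed replicate 2), and without unstressed replicate 3 the difference was -1.15. The probe of miR-207 used here has the sequence GAGGGAGGAGAGCCAG. The array annotation gives it no position, and in the gene table of assembly GRCm38.p6 Mir207 lies within the span of Dnaja1, which encodes a DnaJ family cochaperone.

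**Figure D4:**
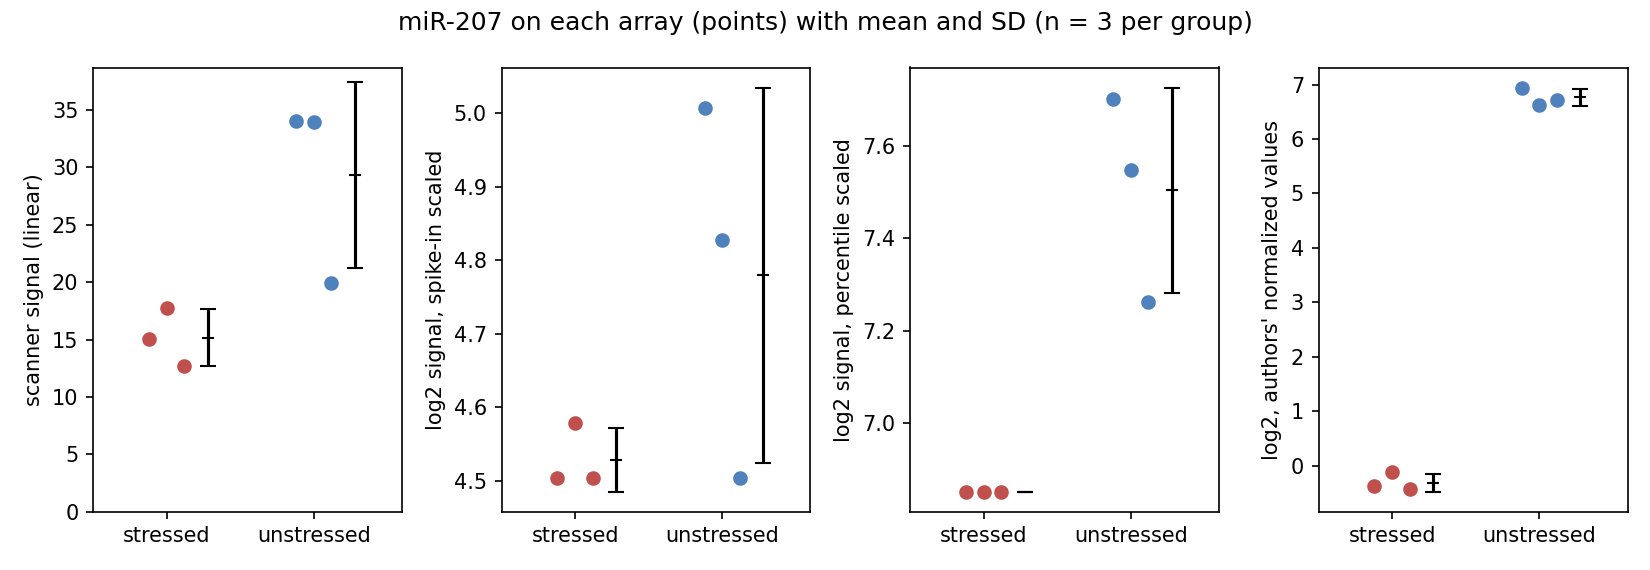
miR-207 on each array (points) with mean and SD (n = 3 per group) as scanner signal, as log2 signal after hybridisation spike-in scaling, as log2 signal after percentile scaling and as the authors' normalized log2 value, each panel with its own vertical axis. The unstressed mean lies above the stressed mean in every panel, and the gap is 7.07 in the authors' values and 0.25 with spike-in scaling, where the call was lost. In that scaling stressed replicates 1 and 3 and unstressed replicate 3 lie at the floor, which limits the gap.

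The values normalized by the authors were compared as a further measure of the same arrays. Over the 431 tested miRNAs limma called 354 higher and 46 lower in stressed exosomes on the deposited log2 values, with a median difference of 3.02. In these values miR-207 fell by 7.07 (SE 0.12, adjusted p = 3.3e-08), from 6.76 ± 0.16 in unstressed to -0.31 ± 0.17 in stressed exosomes (SD, n = 3). The raw totals beside them in the same deposited table were 10.9 ± 3.36 and 6.71 ± 1.80 (exact two-sided permutation p = 0.2). By raw total miR-207 stood at position 27, 33 and 30 from the brightest on the unstressed arrays and at position 459 on stressed replicate 1, 420 on replicate 2 and further down on replicate 3. miR-877-3p fell by 7.26 in the deposited values. Of the 46 miRNAs called lower in the deposited values, 34 were called higher on the unscaled scanner values. The 4 spike-ins differed (stressed minus unstressed) by -5.71 (dmr_3), -6.94 (dmr_6), -6.12 (dmr_285) and -6.78 (dmr_31a) in the deposited log2 values. Without a filter on low signal, limma called 425 miRNAs higher and 1395 lower in the deposited values, and the 1395 included all 1319 miRNAs that the deposited table marks as detected on no array, which had a median difference of -0.91.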

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

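Of the tests in this part, only the one on probes with GGAGG was set before its result was seen; every other test was chosen only after the result was seen, as was the fixed set of miRNAs used for the other splits of the arrays. A signal in probes outside the mouse miRNA comparison was higher on the stressed arrays for 6 control probes. hur_2 read 227007 ± 4349 on the stressed and 32.5 ± 17.2 on the unstressed arrays (SD, n = 3), hur_1 1931 ± 89.3 and 11.9 ± 14.1, mr_1 273.6 ± 12.8 and 2.13 ± 0.933, hur_6 244.8 ± 10.3 and 9.75 ± 1.79, and hur_4 189.5 ± 3.42 and 2.86 ± 0.251. The corner probe miRNABrightCorner30 read 67.1 ± 15.4 and 24.5 ± 15.4. The exact two-sided permutation p was 0.1 for each, the smallest 3 arrays against 3 can give.

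The first pattern weighed is that the unstressed arrays lay near background. Against a failed hybridisation or scan, the spike-ins dmr_3 and dmr_6 differed by -0.39 on the log2 scale in the mean (stressed minus unstressed), and against a failed labelling, dmr_285 and dmr_31a differed by 0.076. The unscaled log2 difference was taken over the 18 miRNAs detected on all 6 arrays whose probes hold neither a repeat nor GGAGG. Its quartiles lay 3.46 apart (largest SE 0.282). For 4 of the 18 the unstressed mean was over 5 times the floor, and their differences ran from 2.82 (miR-6904-5p) to 9.83 (miR-5110). This spread argues against a loss of all signal in the same proportion only if the unstressed signal came from these miRNAs. Other labelled RNA bound to the probes could spread the differences too and was not measured, so such a loss is not excluded. Less labelled RNA of most kinds on the unstressed arrays is a candidate explanation, since the 5 control probes above background in a group, other than spike-in and corner probes (hur_1, hur_2, hur_4, hur_6 and mr_1), were all dimmer there, while hur_5 was at background in both groups. The smallest of the 5 log2 differences was 4.67, for hur_6. The unstressed means of hur_1, hur_4, hur_6 and mr_1 lay under the lowest signal of a detected probe (14.5 in the mean of the unstressed arrays), so the sizes for these are not exact. Stress of the donor mice stays open, because 0 rows of the slide held both groups, so that neither the row nor the yield of the exosome preparations can be told apart from the group.

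The second pattern is the large fall of miR-207 in the deposited values. The authors' values equalled quantile normalization of the log2 raw totals. The raw total of miR-207 was 1.62-fold higher in unstressed exosomes (exact two-sided permutation p = 0.2). Most of the fall of 7.07 on the log2 scale thus arose in that normalization. Spike-ins that were near equal on the scanner were lower in those values too, the mean difference of the 4 spike-ins being -6.38. The explanations below concern the smaller difference that was there before it. Binding of labelled RNA other than miR-207 to its purine-rich probe stays open: the 52 other miRNAs whose probes hold GGAGG read 2.25 units brighter in the median on the unstressed arrays than other probes (SD 0.619 over arrays; one-sided permutation p = 0.0001 over probe labels, the smallest these resamples can give), but miR-207 at 29.3 lay above their 95th percentile of 21.9. Their unstressed median of 2.14 lay under the lowest signal of a detected probe (14.5 in the mean of the unstressed arrays), and 3 were detected on all unstressed arrays. On the stressed arrays GGAGG probes were brighter too, with medians of 1.80 against 0.987. The p-value over probe labels does not measure the spread between arrays. A change with stress also stays open, as miR-207 differed by -0.25 with spike-in scaling and did not pass.

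The third pattern is the fall of miRNAs with repeat-rich sequence after percentile scaling. Probes of 12 of the 22 lower miRNAs hold a dinucleotide repeat (CA or GT), against 41 of the 431 tested, a class defined after such repeats had been noticed. Only the 104 miRNAs above the floor on some array could be called. Among these 104, 16 members of the Sfmbt2 families and 5 other miRNAs had a repeat probe, so the share over all 431 overstates the contrast. Binding to the repeat itself stays open: of 19 tested repeat-probe miRNAs outside the Sfmbt2 families, 14 lay at the floor on all arrays after scaling, so that their median difference of 0 decides nothing, and 4 were called lower. Division by the 75th percentile set the direction of part of the 22, as its scale factors differed between the groups by 5.34 on the log2 scale for every miRNA alike. Without it 12 of the 22 were called higher in stressed exosomes, and these turned by construction. Which of the 2 directions holds for them stays open. It did not set the direction of the 8 that were called lower without it, and 2 were not called without it. A change of the cluster's miRNAs stays open, because 0 tested members above the floor had a probe without such a repeat.

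The other ways of dividing the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. All splits were run on the same 431 miRNAs, which are those detected on at least 3 arrays of any group. As many calls as the real 63 higher and 22 lower miRNAs were given by 1 of the 10 splits each, the real one, and the highest other split gave 0. The same values were 1 split and 0 for the 40 higher and 12 lower miRNAs at a 2-fold difference, and 1 split and 0 for the 354 higher and 46 lower in the deposited values. For the 2 lists called by camera, 10 of the 10 splits gave as many, and the highest other gave 2.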

How the results depend on the processing

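Spike-in scaling and the ways of handling miRNAs at the floor were chosen only after results had been seen; the other alternatives were planned. Signal over background limits these results: on the unstressed arrays few miRNAs were measured, and the level of the floor after scaling sets what can be called. A block for the slide was not run, as there was 1 slide. Among single named miRNAs, 989 alternative values kept direction and side of the threshold, 128 came past it, 24 no longer passed and 20 reversed. Of the 24, miR-466i-3p gave 10 and miR-467f gave 8. For the 2 lists 50 kept their call and 4 lost it. The cause was not tested for any of the following.

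Normexp background gave 29 higher and 13 lower miRNAs, 19 and 4 at a 2-fold difference, and -0.10 for miR-207. Quantile normalization gave 384 higher, and 210 and 26 at 2-fold. The percentile over all probes gave 134 higher and 11 lower, 107 higher at 2-fold, -0.78 for miR-207 (no longer passed) and 0.28 for miR-6918-5p. Without scaling 415 were higher and 8 lower, 315 and 6 at 2-fold; the values were 1.67 for miR-1187, 0.90 for miR-3082-5p, 1.24 for miR-574-5p, 2.75 for miR-669n, 2.82 for miR-6904-5p and 3.51 for miR-6918-5p. With hybridisation spike-ins 372 were higher and 8 lower, 3.0e+02 (rounded to 2 digits) and 2 at 2-fold, 0 lists were called down, the Sfmbt2 list had a median of 2.33 and lost its call, miR-207 was at -0.25, and the values were 2.07 for miR-1187, 1.30 for miR-3082-5p, 0.39 for miR-466i-5p, 1.64 for miR-574-5p, 3.15 for miR-669n, 3.22 for miR-6904-5p and 3.91 for miR-6918-5p. With labelling spike-ins 406 were higher and 10 lower, 308 and 6 at 2-fold, with 1.58 for miR-1187, 0.81 for miR-3082-5p, 1.15 for miR-574-5p, 2.66 for miR-669n, 2.73 for miR-6904-5p and 3.42 for miR-6918-5p. The mean over probes gave -0.44 for miR-207, and the total gene signal 20 lower at 2-fold.

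With no filter on low signal miR-207 stayed at -0.65 but no longer passed, and 1395 miRNAs were lower in the deposited values. With detection required on all arrays 8 were higher at either threshold, 0 lists were called down (median of the Sfmbt2 list -0.59), and the deposited values gave 5 higher and 22 lower. With the positive-and-significant flag 204 were higher and 158 lower, 158 and 115 at 2-fold, the groups differed by 459 detected miRNAs, and 19 were detected in unstressed exosomes only; with the gene detection call the groups differed by 429, and with detection on at least 2 of 3 arrays 12 were seen in unstressed exosomes only. A floor 0.5 times as high gave 45 lower, and 64 and 33 at 2-fold; a floor 2 times as high gave 37 higher and 9 lower, 22 and 6 at 2-fold, and 0 for miR-207. The deposited table and the series matrix each gave 354 higher and 46 lower, 354 and 45 at 2-fold, and 0 lists called up (median of the GC-rich list 6.56). With an estimated correlation camera called 0 lists up and 0 down after percentile scaling, without scaling and with hybridisation spike-ins, but 1 down in the deposited values (the Sfmbt2 list, adjusted p = 0.0162).

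Leaving out each array in turn gave 62 to 90 higher and 13 to 39 lower miRNAs, 40 to 65 and 12 to 22 at 2-fold, -1.15 to -0.55 for miR-207, 1 to 1 lists called up and 1 to 1 down, 353 to 365 higher and 46 to 57 lower in the deposited values, a difference of 380.5 to 393 detected miRNAs, and 376 to 388 miRNAs in stressed and 7 to 12 in unstressed exosomes only. The highest counts of called miRNAs, and the 12, came without unstressed replicate 3, except the 365, which came without unstressed replicate 1. Without stressed replicate 1, 2 or 3, 13, 13 and 14 miRNAs were lower, and the call of miR-207 was lost without any of these or without unstressed replicate 2.

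Whether the replicate numbers pair the samples is not settled by 3 arrays per group. Same-numbered arrays correlated at 0.228, -0.199 and 0.300 in their deviations from the group means. Replicates 1 and 3 correlated best with their own number (highest with another, -0.025 and 0.185), and replicate 2 correlated better with another number (0.289). With the replicate number as a block 61 miRNAs were higher and 17 lower, 40 and 12 at 2-fold, miR-207 was at -0.65 (adjusted p = 0.0419; 3.1e-09 to 1 over all alternatives), 1 list was called up and 1 down, and 353 and 46 were called in the deposited values; no count moved by over 1.5 times, though 63 higher and 22 lower were called without the block.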

Other observations

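No test was added for this part, and the sequence kinds it names were noticed only after the values had been seen. The miRNAs named for their signal in unstressed exosomes were measured on all 6 arrays. miR-466i-5p read 1547 ± 640 in unstressed and 1453 ± 212 in stressed exosomes (scanner signal, SD, n = 3). The values were 435 ± 178 and 973 ± 149 for miR-574-5p, 424 ± 150 and 766 ± 137 for miR-3082-5p, 176 ± 64.0 and 542 ± 86.7 for miR-1187, and 239 ± 33.4 and 216150 ± 2671 for miR-5110, unstressed before stressed. Between the groups miR-5110 thus differed by 9.83 on the log2 scale without scaling, and miR-466i-5p by -0.01.

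The 8 miRNAs called lower in stressed exosomes without scaling were of 2 sequence kinds: 6 have probes with a GT repeat, such as miR-466h-3p with GTGTGTGTGTGCGT, and 2, miR-207 and miR-877-3p, have probes with GGAGG. miR-877-3p, with the probe TGGGAGGAGGGAGAAGA, read 21.4 ± 2.47 in stressed and 40.8 ± 10.2 in unstressed exosomes (SD, n = 3). The scanner software used its default spot size on all 3 unstressed arrays and on 0 stressed arrays.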
